A study of Homo sapiens with 15 samples.

How the data were processed

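RNA sequencing was analysed for 15 libraries of PGP1, an established human induced pluripotent stem cell (iPSC) line, either unedited (WT) or with a 40 kb or 100 kb deletion between the genes ROBO1 and ROBO2. Each genotype was sampled as iPSC at day 0, with 3 libraries, and as cells at day 6 of a commercial neural crest differentiation protocol (NCC), with 2 libraries. Per the labels, RNA was taken up in trizol, selected for poly-A tails, reverse transcribed from random hexamers and made into libraries with a Nextera kit. The deposited table holds expected counts per gene symbol for 56707 genes: the authors quantified the reads with Salmon against hg38, as the submitters' processing notes name them. The version of Salmon, the annotation and the way transcripts were summed to genes are not given in the sources used here. The values were not whole in 54.2% of cells of the table, were not scaled to a common total, and were rounded before testing. Every gene name was a gene name of GENCODE release 29 (GRCh38), which gave the identifiers, gene types and positions. Whether the counting used strand is not given, so reads of genes that overlap on opposite strands, and of near-identical gene copies, cannot be told apart.

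Library totals ran from 24.66 to 45.9 M estimated counts, M being 10 to the power 6. At this depth a gene at 10 CPM is well measured in each library, whereas values far below 1 CPM rest on few fragments, so for genes with at most 3 counts summed over a group only levels are given and no fold change. In simulated data with the same group sizes and dispersions, the test called 59.7%, 65.7% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold in iPSC, and 40.3%, 73.1% and 89.4% in NCC. Calls on unchanged genes made up 3.3% and 5.9% of all calls in those simulations. The changed genes were drawn from those at 1 CPM or more, so the rates do not cover weaker genes. Each rate rests on 66 or 67 genes of a single run, in which a list of p53 target genes was also raised 2-fold.

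Libraries were grouped by genotype and state as the labels give them. Genes were filtered with filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and 1 quasi-likelihood model of 6 groups with 9 residual degrees of freedom was fitted in edgeR 4.0.16 (R 4.3.3). This left 24574 genes, with a common dispersion of 0.0247. Genes with a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test are called changed, and the standard error (SE) of a log2 fold change was derived from its F statistic. The comparisons were NCC against iPSC in each genotype, each deletion against WT in each state, the 100 kb against the 40 kb deletion in each state, and the interaction of deletion with differentiation. Levels are given as TMM-scaled CPM. Sets of genes were tested with camera in limma 3.58.1 with a preset correlation of 0.01, on 34 gene lists, with p adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. The comparisons, the gene lists, the rule for naming genes and the alternative settings below were fixed before the data were examined. The rule took ROBO1, ROBO2 and their listed neighbours in every comparison. It also took up to 10 protein-coding genes per direction with the largest change, at least 10 CPM in a group and no overlap between the libraries of the compared groups. To these it added up to 4 members per list and up to 10 genes changed in both deletions per state, each by the smallest adjusted p, and up to 5 genes per interaction. Genes named outside this rule are said to be so.

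The fold changes of the deletions share their WT libraries. For their correlation and covariance, counts of all 15 libraries were simulated 20 times, with each deletion group at the WT mean of its state. The simulated deletion groups thus shared simulated WT libraries, not the real ones. Genes were drawn independently, so deviations that genes share in the real WT libraries are left out of this baseline. Principal components used 14624 genes with a mean log2 CPM over 1. These alternative settings were RLE scaling, DESeq2 1.42.0, no filter on low counts, a stricter filter, fits on only the libraries of the compared state or genotype, the replicate number as a block, leaving out each library in turn, and a threshold of 2-fold. Scaling by library totals alone, removal of trends with GC content and transcript length, and thinning to the smallest library were added after seeing the data. The labels do not say whether replicates are separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical. For the same reason a difference between clones or differentiation runs is not separated from a deletion in any comparison with WT, the interactions included. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.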

Results

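The data covered PGP1, an iPSC line able to form all embryonic tissues, and NCC made from it. Neural crest is the embryonic population that gives rise to much of the facial skeleton and to peripheral neurons, glia and pigment cells. The study concerns microtia, a malformation of the outer ear, and the edited interval lies in the intergenic DNA between ROBO1 and ROBO2, which encode receptors for SLIT guidance proteins. The endpoints of the deletions and the number of edited alleles are not given in the sources used here. Among iPSC, totals were 32.99 to 45.22 M counts in WT, 33.59 to 39.02 M in the 40 kb line and 34.53 to 38.24 M in the 100 kb line. Among NCC they were 25.34 and 45.9 M in WT, 31.15 and 33.93 M in the 40 kb line, and 24.66 and 24.89 M in the 100 kb line. Levels are CPM as mean ± SD over 3 iPSC or 2 NCC libraries, and changes are log2 fold changes ± SE with edgeR's adjusted p.

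Cell state was the main axis of expression, and WT NCC stood apart from NCC of both deletion lines. The first principal component held 81.3% of the variance and separated iPSC from NCC. The second held 8.2%, with WT NCC at 50.1 and 54.7 and the 4 deletion NCC libraries between -37.6 and -24.

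**Figure D1:**
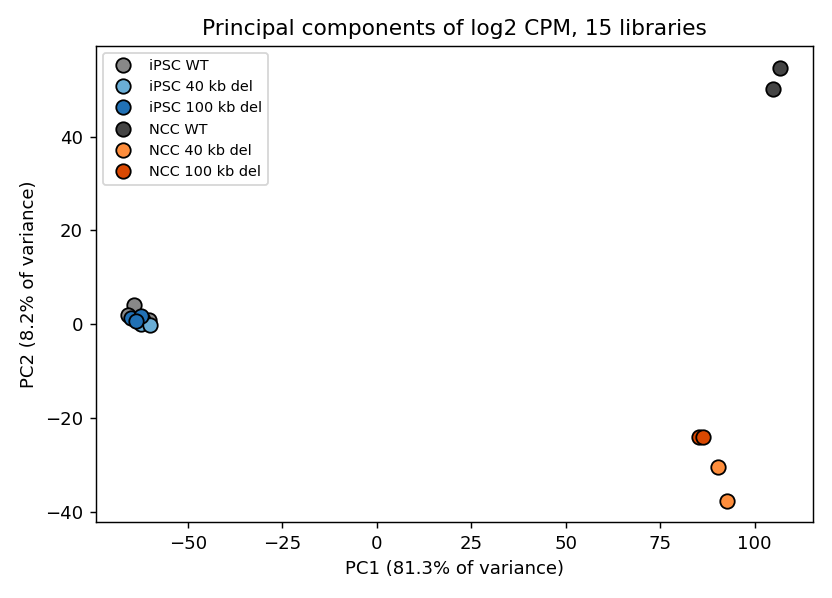
Each point is a library placed by its scores on the first and second principal components of log2 CPM (no unit). The 9 iPSC libraries lie together on the left, while on the second component the 2 WT NCC libraries, at 50.1 and 54.7, lie above the 4 deletion NCC libraries.

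The comparison of NCC with iPSC in WT shows what differentiation did in unedited cells. Pluripotency genes fell in 34 of 36 measured members. POU5F1, a core pluripotency factor, went from 1229 ± 51.2 to 5.52 ± 0.525 CPM (log2 -7.81 ± 0.12, adjusted p = 6.41e-16). TDGF1, a NODAL co-receptor, went from 664 ± 37.6 to 0.148 ± 0.0509 CPM (-12.01 ± 0.19). NANOG, another core factor (-9.65 ± 0.27), and PRDM14, a repressor of differentiation (-10.66 ± 0.27), fell. Neural crest specifiers rose in 24 of 30 members, including SOX10 (8.10 ± 0.926 to 306 ± 14.9 CPM) and the adhesion gene CDH6 (2.42 ± 0.986 to 439 ± 17.0 CPM). TFAP2B and NR2F1, transcription factors of the crest, rose by 10.46 ± 0.37 and 9.53 ± 0.34. Genes of neurons and glia rose in 24 of 27 members, with NEUROD1 and NEUROG1, which drive sensory neuron formation, up by 9.63 ± 0.30 and 9.15 ± 0.48, and the neuronal cytoskeletal gene DCX up by 3.92 ± 0.15.

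In the same comparison the neural plate border list rose in 17 of 21 members, led by PAX3 (8.08 ± 0.32) and TFAP2A (8.07 ± 0.34), while ZIC5, also expressed in iPSC, fell by 3.66 ± 0.13. Ectomesenchyme and arch genes rose in 22 of 33 members, with the collagen gene COL1A2 reaching 2433 ± 8.08 CPM. Migration genes rose in 20 of 25, including VIM, an intermediate filament gene of migratory cells (2.81 ± 0.08), and CXCR4, a chemokine receptor (5.77 ± 0.19). Genes of glycolysis and hypoxia fell in 24 of 34 members, such as HK1 (-2.08 ± 0.06) and ALDOC (-3.65 ± 0.12). Genes at the floor in 1 state are given as levels: the glutamate receptor gene GRIA2 went from 0.0174 ± 0.0156 to 30.02 ± 1.77 CPM, FOXD2 from 0.0157 ± 0.0137 to 15.5 ± 0.534, RAB7B from 0.00734 ± 0.0127 to 10.01 ± 0.385 and MAB21L4 from 0.0184 ± 0.0162 to 12.8 ± 0.0736. NKX1-2 went from 45.3 ± 2.85 to 0.0391 ± 0.00253 CPM and DPEP3 from 16.4 ± 2.30 to 0.0102 ± 0.0144. Other genes of the largest rises were the sodium channel gene SCN3A (9.72 ± 0.56) and GREB1L (9.65 ± 0.46), and other large falls were FOXH1 (-9.80 ± 0.27), ZSCAN10 (-9.37 ± 0.18), HHLA1 (-9.34 ± 0.24), SPTSSB (-9.52 ± 0.48) and C13orf42 (-10.11 ± 0.25).

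Across all genes, 14036 of 24574 changed between WT NCC and WT iPSC, 7067 higher and 6969 lower in NCC. The pluripotency (camera adjusted p = 1.33e-20), crest specifier (1.84e-07) and ectomesenchyme (0.00013) lists passed, with adjusted p = 0.000887, 0.00498 and 0.0233 with an estimated correlation. The lists of neurons and glia (7.14e-08), plate border (0.000243), migration (8.93e-07) and glycolysis (1.47e-05) also passed, but with adjusted p = 0.0504, 0.136, 0.0623 and 0.192 with an estimated correlation. With p adjusted over the list alone, the counts were 34 lower for pluripotency, 24 higher for crest specifiers, 23 for ectomesenchyme, 24 for neurons and glia, 17 for plate border, 20 for migration and 24 lower for glycolysis. Members that went the other way, named after their values were seen, included MYCN (0.98 ± 0.09) in the pluripotency list, B3GAT1 (-1.10 ± 0.10) and MYC (-2.74 ± 0.32) among crest specifiers, SYT1 (-2.40 ± 0.14) and DLL3 (-0.49 ± 0.16) among neuron and glia genes, and in the plate border list ZIC2 (-3.15 ± 0.17) and GBX2 (-1.48 ± 0.47) beside ZIC5. Others were BARX1 (-6.22 ± 0.57), LHX6 (-3.94 ± 0.51), LHX8 (-2.96 ± 0.92) and SIX2 (-1.85 ± 0.42) in the ectomesenchyme list, CDH1 (-1.18 ± 0.08), ITGB1 (-0.30 ± 0.09) and ADAM10 (-0.49 ± 0.09) in the migration list, and NDRG1 (0.70 ± 0.16) and LDHB (0.37 ± 0.09) in the glycolysis list.

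ROBO2 was a differentiation-induced gene in WT, and in both deletion lines its level in NCC was near its iPSC level. ROBO2 (ENSG00000185008, chromosome 3, 75906695 to 77649964, plus strand, GRCh38) rose from 11.4 ± 1.07 CPM in WT iPSC to 61.6 ± 3.19 in WT NCC (log2 2.43 ± 0.16, adjusted p = 1.97e-09). It measured 7.18 ± 1.07 CPM in 40 kb NCC and 12.5 ± 0.979 in 100 kb NCC, lower than WT NCC by -3.10 ± 0.19 (adjusted p = 1e-08) and -2.30 ± 0.18 (2.2e-07). ROBO1 (ENSG00000169855, chromosome 3, 78597240 to 79767815, minus strand) rose from 236 ± 4.27 to 345 ± 3.83 CPM in WT (0.55 ± 0.08, adjusted p = 2.9e-05). In NCC it fell to 186 ± 26.6 CPM with the 40 kb deletion (-0.89 ± 0.09, 2.15e-06) and to 221 ± 9.65 with the 100 kb deletion (-0.65 ± 0.09, 7.92e-05). Every deletion NCC library lay below both WT NCC libraries for both genes.

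In iPSC neither gene passed against WT. ROBO2 measured 9.61 ± 1.09 CPM in the 40 kb line (-0.25 ± 0.15, adjusted p = 0.317) and 12.7 ± 2.60 in the 100 kb line (0.15 ± 0.15, 0.703), and ROBO1 measured 235 ± 1.54 (-0.01 ± 0.07, 0.957) and 214 ± 15.6 (-0.14 ± 0.07, 0.423). Differentiation changed ROBO2 by -0.42 ± 0.17 in the 40 kb line (adjusted p = 0.0504) and by -0.02 ± 0.17 in the 100 kb line (0.932), and ROBO1 by -0.34 ± 0.08 (0.00294) and 0.04 ± 0.08 (0.698). Between the deletions in NCC, ROBO2 differed by 0.80 ± 0.19 (adjusted p = 0.0573) and ROBO1 by 0.25 ± 0.09 (0.246), the 100 kb line having the larger means. In edgeR's test of the interaction, the difference from WT was not the same in NCC and iPSC. This held for ROBO2 (-2.85 ± 0.24, adjusted p = 4.26e-07, in the 40 kb line and -2.45 ± 0.23, 2.46e-06, in the 100 kb line) and for ROBO1 (-0.88 ± 0.12, 5.07e-05, and -0.50 ± 0.12, 0.00837).

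**Figure D2:**
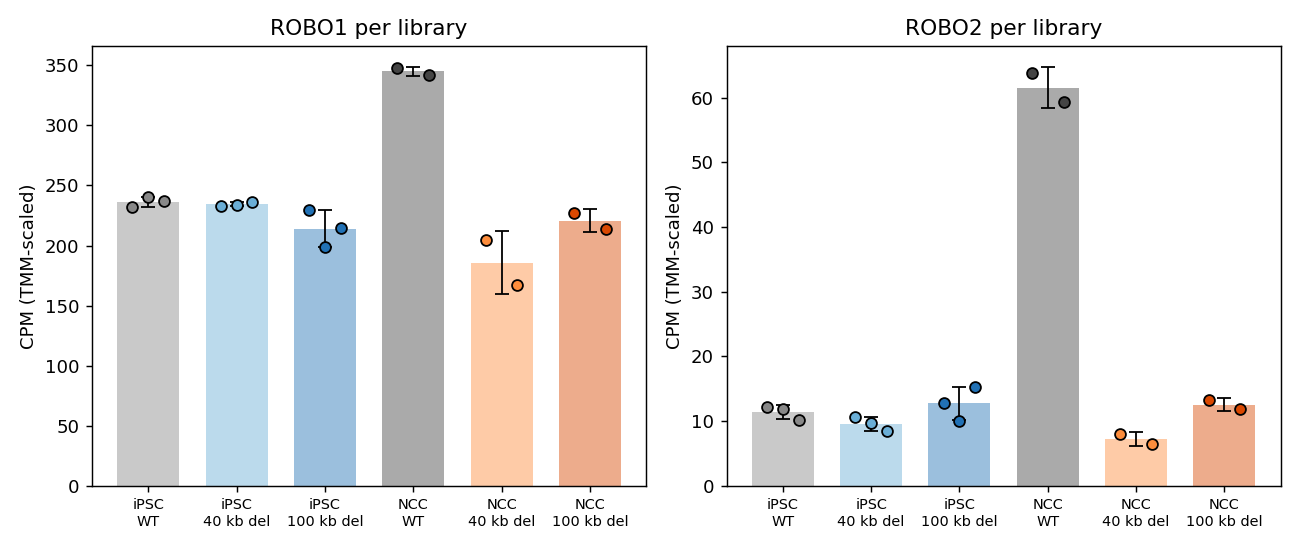
Bars show the mean TMM-scaled CPM of ROBO1 (left) and ROBO2 (right) per group, error bars the SD and points the libraries (3 per iPSC group, 2 per NCC group). ROBO2 reached 61.6 CPM in WT NCC and stayed between 7.18 and 12.7 CPM in the other NCC and iPSC groups.

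Among 21 measured genes of chromosome 3 around the locus, those 2 included, 8 changed in 40 kb NCC and 6 in 100 kb NCC, where 24% and 19.9% of all tested genes changed. In NCC of both lines VGLL3, a transcription cofactor (1.03 ± 0.21 and 0.64 ± 0.21), CHMP2B, of the endosomal sorting complex (1.02 ± 0.13 and 0.64 ± 0.13), and RYBP, of Polycomb complex 1 (0.75 ± 0.11 and 0.56 ± 0.11), rose. HTR1F went from 0.442 ± 0.0975 CPM in WT to 0.0497 ± 0.0257 and 0.0628 ± 0.0291. PDZRN3 (-0.64 ± 0.15) and ZNF717 (-2.27 ± 0.70) fell in 40 kb NCC, and measured -0.33 ± 0.15 (adjusted p = 0.147) and 1.27 ± 0.57 (0.145) in 100 kb NCC. As a list the neighbours did not pass (camera adjusted p = 0.422 and 0.877), and adjusted over the list alone 3 were higher and 6 lower in 40 kb NCC, and 3 higher and 3 lower in 100 kb NCC. In 40 kb iPSC, CHMP2B (0.43 ± 0.10, adjusted p = 0.0187) and PPP4R2 (0.36 ± 0.10, 0.0306) rose and ZNF717 fell (-3.03 ± 0.54, 0.00431). The wider SLIT and ROBO pathway list went both ways, with 8 members higher and 6 lower of 32 in 40 kb NCC and 7 and 7 in 100 kb NCC (camera adjusted p = 0.705 and 0.933). Adjusted over the list alone, these were 10 and 8, and 8 and 7. CDC42, a small GTPase of the pathway, rose by 0.78 ± 0.10 and 0.61 ± 0.10.

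As lists, neuron and glia genes were lower in NCC with the 40 kb deletion than in WT NCC, and pluripotency and placode and surface ectoderm genes were higher. Genes of neurons and glia fell in 20 of 27 members, such as the neurofilament gene NEFM, from 155 ± 1.495 to 7.11 ± 0.166 CPM (-4.44 ± 0.13, adjusted p = 1.67e-11), NEUROD1 (-5.60 ± 0.26) and DCX (-3.52 ± 0.18), while GAP43 (0.71 ± 0.15) and SYT1 (0.62 ± 0.14), singled out after their values were seen, rose. Among the largest falls, the RNA-binding gene ELAVL3 went from 70.2 ± 0.981 to 0.342 ± 0.0513 CPM, the neuropeptide gene SST from 38.8 ± 2.09 to 0.382 ± 0.228, GRIA2 from 30.02 ± 1.77 to 0.0824 ± 0.0274. SYT4, PCDH15, PPP1R17, ATP2B2, PRSS56, NTN5 and THSD7B fell by 6.23 to 8.12. NOTCH pathway genes fell in 12 of 22 members, with DLL3, also in the neuron list, down by 4.31 ± 0.22 and the effector HEYL by 4.10 ± 0.33. Pluripotency genes rose in 22 of 36 members. POU5F1 went from 5.52 ± 0.525 to 29.6 ± 2.69 CPM (2.43 ± 0.11), against 1229 ± 51.2 in WT iPSC. PODXL, a surface sialomucin, went from 161 ± 17.5 to 931 ± 32.4 (2.53 ± 0.08), and ESRG, a transcript abundant in pluripotent cells, from 3.96 ± 0.546 to 59.4 ± 11 (3.88 ± 0.16).

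In the same cells placode and surface ectoderm genes rose in 15 of 29 members, with the keratin genes KRT8 (1257 ± 63.7 to 4160 ± 110 CPM), KRT18 (1.63 ± 0.10) and KRT19 (1.61 ± 0.10). Falls in that list included EYA2 (-2.60 ± 0.22) and EYA1 (-0.96 ± 0.21), placodal regulators named after their values were seen. Neural crest specifiers went both ways, 9 higher and 9 lower of 30: SOX10 fell from 306 ± 14.9 to 104 ± 37.1 CPM (-1.56 ± 0.18), ERBB3 by 1.66 ± 0.15 and ITGA4 by 3.06 ± 0.35, while ANXA2 rose by 1.13 ± 0.09. FGF and MAPK targets rose in 14 of 22 members, such as SPRY4 (2.95 ± 0.14) and ETV4 (2.62 ± 0.12), and immediate early and heat shock genes in 21 of 30 (FOSL1, 2.93 ± 0.24). The p53 targets rose in 18 of 28 (CDKN1A, 1.43 ± 0.15) and interferon and antigen presentation genes in 16 of 28 (IFITM1, 1.71 ± 0.11). Unfolded protein and integrated stress genes rose in 21 of 30 (ASNS, 1.70 ± 0.21) and glycolysis and hypoxia genes in 19 of 34 (PFKP, 1.48 ± 0.08). The largest rises included LHX5 (4.50 ± 0.48), ZSCAN10 (4.45 ± 0.19), F2RL2 (3.68 ± 0.49), MT2A (3.41 ± 0.22), RAB17 (3.41 ± 0.20), FLT1 (3.40 ± 0.15), SYT6 (3.36 ± 0.23), SALL3 (3.33 ± 0.26) and FST (3.29 ± 0.20).

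Members going the other way, named after their values were seen, were MYCN (-0.47 ± 0.10) and SFRP2 (-1.03 ± 0.12) in the pluripotency list and DUSP4 (-0.81 ± 0.16) and ETV1 (-0.82 ± 0.18) in the FGF list. Over all genes 5898 changed in 40 kb NCC, 3427 higher and 2471 lower, 2528 of them by 2-fold or more. Of the called genes 58.1% were higher with TMM and 35.5% with library totals, where the median log2 fold change of all genes was -0.009 and -0.185. Camera passed for neurons and glia (adjusted p = 6.89e-14), pluripotency (1.38e-09), placode (1.89e-06), NOTCH (0.000132), FGF (2.41e-06), immediate early (2.31e-09), p53 (4.1e-08) and interferon (6.13e-08) lists, with adjusted p = 0.0157, 0.0157, 0.0349, 0.0482, 0.0482, 0.0368, 0.0368 and 0.0349 with an estimated correlation. The stress (3.97e-08) and glycolysis (5.52e-06) lists had adjusted p = 0.173 and 0.173 with an estimated correlation, and crest specifiers did not pass (0.714). With p adjusted over the list alone, 20 neuron and glia and 12 NOTCH genes were lower, and 23 pluripotency, 17 placode, 14 FGF, 23 immediate early, 19 p53, 17 interferon, 24 stress and 19 glycolysis genes were higher, with crest specifiers at 10 higher and 13 lower.

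NCC with the 100 kb deletion showed the neuronal and pluripotency changes too. Genes of neurons and glia fell in 20 of 27 members, with NEFM at 9.74 ± 0.151 CPM (-3.99 ± 0.13, adjusted p = 6.2e-11), NEUROD1 at 2.27 ± 0.496 (-5.19 ± 0.26) and DCX lower by -2.94 ± 0.17, while GAP43 rose (0.68 ± 0.15, named after its value was seen). SST went from 38.8 ± 2.09 to 0.0834 ± 0.118 CPM, GRIA2 to 0.126 ± 0.00119 and ELAVL3 to 1.45 ± 0.637, and PCDH15, PPP1R17, SYT4, THSD7B, ATP2B2, PRSS56 and NTN5 fell by 5.55 to 7.47. Pluripotency genes rose in 21 of 36 members, with POU5F1 at 38.03 ± 3.83 CPM (2.80 ± 0.11), PODXL at 776 ± 4.67 (2.27 ± 0.08), ESRG at 90.2 ± 1.21 (4.49 ± 0.16) and VRTN at 20.9 ± 1.36 (3.68 ± 0.14). Placode and surface ectoderm genes rose in 16 of 29, such as KRT8 (1.37 ± 0.08), FOXI3 (2.0 ± 0.13) and CDH1, the epithelial cadherin (1.16 ± 0.09). NOTCH genes fell in 12 of 22, including HES6 (-2.99 ± 0.15) and HEYL (-3.77 ± 0.33). Crest specifiers were split, 8 higher and 9 lower of 30, with ERBB3 (-1.29 ± 0.14) and CDH6 (-1.61 ± 0.21) lower and NGFR, the low-affinity neurotrophin receptor (0.89 ± 0.12), higher.

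Further rises in 100 kb NCC were of FGF and MAPK targets in 12 of 22 members (SPRY4, 2.41 ± 0.14), interferon genes in 14 of 28 (IFITM1, 2.02 ± 0.11), p53 targets in 14 of 28 (CDKN1A, 0.92 ± 0.15) and immediate early genes in 13 of 30 (FOSL1, 1.96 ± 0.24). The list of stress genes rose in 19 of 30 (ASNS, 1.48 ± 0.21) and glycolysis and hypoxia genes in 15 of 34. The largest rises included LHX5 (5.58 ± 0.49), ZSCAN10 (4.94 ± 0.19), FST (4.06 ± 0.21), DLK1 (3.93 ± 0.40), VRTN, SALL3 (3.52 ± 0.26), SYT6 (3.52 ± 0.24), CDH23 (3.44 ± 0.27) and FLT1 (3.43 ± 0.15). Members going the other way, named after their values were seen, included SFRP2 (-0.81 ± 0.12) of the pluripotency list, EYA1 (-0.77 ± 0.21), EYA2 (-2.35 ± 0.22) and CRABP2 (-0.27 ± 0.09) of the placode list, and NOTCH3 (0.27 ± 0.09) and DLL4 (1.60 ± 0.48) of the NOTCH list. Others were DUSP4 (-1.06 ± 0.16) and SPRED1 (-0.39 ± 0.12) of the FGF list, BTG2 (-0.62 ± 0.15) of the p53 list and CRELD2 (-0.43 ± 0.12) of the stress list. In all, 4891 genes changed, 2833 higher and 2058 lower, of which 57.9% were higher with TMM and 37% with library totals, where the median of all genes was 0 and -0.139. By 2-fold or more, 2008 changed. The count was 3190 without WT NCC replicate 1 and 3251 without 100 kb NCC replicate 1. Camera passed for pluripotency (adjusted p = 7.36e-15), neurons and glia (2.24e-14) and placode (1.24e-06), with adjusted p = 0.00318, 0.015 and 0.0355 with an estimated correlation. It passed for NOTCH (2.12e-05), FGF (4.34e-05), interferon (2.17e-05), p53 (4.34e-05), immediate early (2.47e-05), stress (3.1e-06) and glycolysis (4.14e-06) lists, whose adjusted p = 0.0519, 0.118, 0.0878, 0.133, 0.141, 0.234 and 0.204 with an estimated correlation. Adjusted over the list alone, 24 pluripotency, 18 placode, 14 FGF, 14 interferon, 16 p53, 18 immediate early, 20 stress and 16 glycolysis genes were higher, 20 neuron and glia and 13 NOTCH genes were lower, and crest specifiers stood at 11 higher and 10 lower. Crest specifiers did not pass as a list (camera adjusted p = 0.909).

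**Figure D3:**
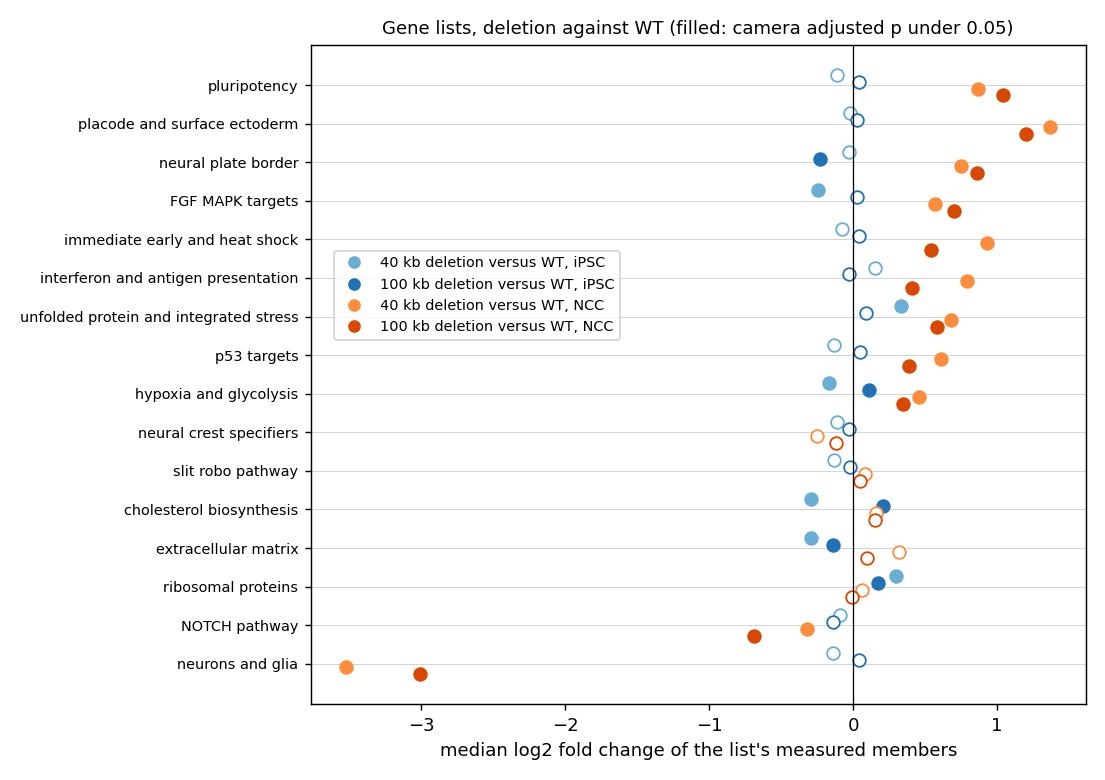
Each point is the median log2 fold change of a gene list's measured members in a deletion against WT, in iPSC (blue) or NCC (orange), filled where the camera adjusted p with a preset correlation is under 0.05. Neuron and glia genes had medians of -3.52 and -3.01 in NCC of the 40 kb and 100 kb lines, and pluripotency genes 0.87 and 1.04, while with library totals in place of TMM the medians of the SLIT and ROBO list in NCC of both lines, of cholesterol genes in 40 kb NCC, of matrix genes in 100 kb NCC, of ribosomal genes in 40 kb NCC, and of plate border and placode genes in 40 kb iPSC change sign, and that of FGF genes in 100 kb iPSC becomes 0.

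The deletions overlapped widely in NCC. In the same direction 3915 genes changed in both lines, 2355 higher and 1560 lower, and 6 changed in opposite directions. NEFM, COLGALT2 (-4.32 ± 0.15 and -4.29 ± 0.15), C14orf132 (-3.43 ± 0.11 and -3.24 ± 0.11), RAB3B (1.70 ± 0.07 and 1.85 ± 0.07) and COL9A3 (2.61 ± 0.10 and 2.35 ± 0.10) were among the genes of smallest adjusted p in both, beside PODXL, ESRG, FLT1, ZSCAN10 and POU5F1. Independent lists of these sizes would share 395.1 higher and 206.9 lower genes. Across 15233 genes, which are not independent replicates, the fold changes of the deletions correlated at 0.88, against 0.47 in the simulations of unchanged groups. Their covariance was 0.596 against 0.0378, a difference of 0.558. The 2 WT NCC libraries are too few to give each deletion its own 2, so part of the excess may come from the shared WT libraries. The simulated WT libraries hold no deviation that genes share in the real ones. A WT clone or differentiation run that differed would also shift both comparisons alike.

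In iPSC the 40 kb line differed from WT in many genes, mostly by small changes. Among the largest rises was that of SLC7A11, a cystine transporter gene, from 49.4 ± 23.2 to 158 ± 28.2 CPM (1.68 ± 0.29, adjusted p = 0.00377). TRIB3 (1.42 ± 0.29), ATF5 (1.33 ± 0.25) and PCK2 (1.14 ± 0.20) rose too, and the unfolded protein and integrated stress list rose in 9 of 30 members. CUZD1 (2.13 ± 0.35), MEF2B (1.87 ± 0.44), the chemokine gene CXCL5 (1.48 ± 0.20), the death receptor gene FAS (1.35 ± 0.18), TSC22D3 (1.29 ± 0.26) and PKDCC (1.07 ± 0.13) also rose. Ribosomal protein genes rose in 18 of 51 members by small amounts (RPL4, 0.31 ± 0.06). Matrix genes fell in 14 of 36 (FN1, -0.41 ± 0.08), cholesterol synthesis genes in 10 of 24 (LSS, of sterol ring formation, -0.50 ± 0.08) and glycolysis and hypoxia genes in 11 of 34 (PKM, -0.44 ± 0.07), where VEGFA (0.84 ± 0.14), ADM (0.66 ± 0.12) and LDHB (0.32 ± 0.08), named after their values were seen, rose. The largest falls under the naming rule were of SULF1, a heparan sulfatase (-1.20 ± 0.10), TFCP2L1, a naive pluripotency factor (-1.13 ± 0.19), MAST3 (-1.33 ± 0.22), IQSEC2 (-1.18 ± 0.16), OPCML (-1.15 ± 0.22), GLTP (-1.12 ± 0.17), SLC16A3 (-1.02 ± 0.17), GRIN2D (-1.0 ± 0.15), LEFTY1 (-1.22 ± 0.36) and HSPA1A (-1.17 ± 0.25). Genes outside that rule fell further, such as ZNF736 (-5.98 ± 0.31), named after its value was seen. The pluripotency list did not pass (camera adjusted p = 0.579), with 3 members higher, FGF2 (0.73 ± 0.10), L1TD1 (0.48 ± 0.07) and, named after its value was seen, LIN28B (0.32 ± 0.07), and 8 lower.

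In that comparison 2294 genes changed, 1033 higher and 1261 lower, 194 of them by 2-fold or more, with 45% of called genes higher with TMM and 63.4% with library totals. The count moved with single libraries: 1525, 889 and 1379 without WT replicate 1, 2 or 3, and 1421, 1281 and 1145 without 40 kb replicate 1, 2 or 3. It was 3569 with DESeq2 and 1417 after trends with GC content and length were removed. LEFTY1 lost its call on leaving out WT iPSC replicate 1, WT NCC replicate 1 or 2, 40 kb iPSC replicate 1 or 2, or 100 kb iPSC replicate 3, and also with the replicate block, with iPSC fitted alone, without GC and length trends and after thinning. Calls were also lost by MEF2B without WT replicate 1 or 2 or 40 kb replicate 1, and by HSPA1A, a near copy of HSPA1B, without WT replicate 2. Camera passed for ribosomal (adjusted p = 6.51e-14), matrix (4.5e-06), cholesterol (0.000201), stress (0.00259) and glycolysis (0.00528) lists, each with adjusted p = 0.556 with an estimated correlation. With p adjusted over the list alone, 37 ribosomal genes were higher, 18 matrix, 11 cholesterol and 15 glycolysis genes were lower, and the stress list had 14 higher and 3 lower, the pluripotency list 5 higher and 10 lower.

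In iPSC the 100 kb line had few called changes against WT. SLC2A14, a glucose transporter gene that is a near copy of SLC2A3, fell from 23.4 ± 1.56 to 6.10 ± 0.998 CPM (-1.94 ± 0.14, adjusted p = 3.95e-06). TFRC, the transferrin receptor, rose from 190 ± 38.8 to 335 ± 28.5 CPM (0.82 ± 0.12), and ZNF736 (1.17 ± 0.20), RAB3GAP2 (0.68 ± 0.10), AMT (0.56 ± 0.07), NAA15 (0.45 ± 0.06) and MAPK6 (0.43 ± 0.07) rose. HTR7, RAB17, FAM221A, ADAMTS14, MYOF, ZNF681, PHF21B, PRAF2 and TRIM4 fell by 0.62 to 0.83. Most of these calls did not withstand leaving out 1 library: 3 of the 6 rises (ZNF736, TFRC and MAPK6) and 9 of the 10 falls, SLC2A14 excepted, were lost. TFRC lost its call only without WT iPSC replicate 2, each of the others without any of several libraries. For FAM221A, ADAMTS14, MYOF and PRAF2 these included libraries outside the comparison, so no single library decided such calls. With iPSC fitted alone ZNF736, MAPK6, FAM221A, ADAMTS14, MYOF and PRAF2 lost their call. So did MYOF and PRAF2 with the replicate block, FAM221A with RLE scaling, and MYOF without GC and length trends and after thinning.

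In all 39 genes changed, 10 higher and 29 lower, and 3289 had an unadjusted p under 0.05. The count was 16 and 25 without WT replicate 2 or 3, 121 and 18 without 100 kb replicate 1 or 3, and 24 when iPSC were fitted alone. DESeq2 called 683, 444 higher and 239 lower, and edgeR without a filter on low counts 844, 420 higher and 424 lower. Without 100 kb replicate 2 it called 24 higher and 16 lower, so neither direction prevailed in every setting. Cell cycle, cholesterol and ribosomal lists passed camera as higher (adjusted p = 4.08e-07, 9.4e-07 and 1.95e-10) though edgeR called 0 of their 36, 24 and 51 members. At an unadjusted p under 0.05, 17, 13 and 18 members were higher, and DESeq2 called 7, 8 and 5. They had adjusted p = 0.256, 0.579 and 0.579 with an estimated correlation, and adjusted over the list alone 13, 10 and 5 members were higher. The member of smallest adjusted p was RRM2, of nucleotide synthesis, at 64.5 ± 1.01 against 31.9 ± 0.649 CPM (1.02 ± 0.20, adjusted p = 0.0599). Matrix genes passed as lower (0.00151, adjusted p = 0.579 with an estimated correlation) with NID2 (-0.50 ± 0.09) and COL5A1 (-0.51 ± 0.09) called, and adjusted over the list alone 2 were higher and 10 lower.

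In iPSC of both deletion lines 12 genes changed against WT in the same direction, 4 higher and 8 lower. FLG, encoding filaggrin, went from 5.91 ± 0.133 CPM in WT to 0.465 ± 0.193 in the 40 kb line and 0.199 ± 0.0643 in the 100 kb line, and the noncoding LINC01108 from 82.7 ± 4.19 to 18.5 ± 2.72 and 35.0 ± 2.31. AMT (0.42 ± 0.07 and 0.56 ± 0.07), NAA15 (0.27 ± 0.06 and 0.45 ± 0.06) and MAPK6 (0.27 ± 0.07 and 0.43 ± 0.07) rose in both. PHF21B, PRAF2, COL5A1 and NID2 fell in both, and MAGEA12 went from 0.873 ± 0.439 CPM to 0.0430 ± 0.0543 and 0.01 ± 0.0174. Another 4 genes, named after their values were seen, went in opposite directions: ZNF736 (-5.98 ± 0.31 and 1.17 ± 0.20), SLC2A14 (0.76 ± 0.13 and -1.94 ± 0.14), RAB17 (0.46 ± 0.12 and -0.80 ± 0.12) and PCDHB17P (-1.23 ± 0.21 and 1.30 ± 0.20). Independent lists would share 0.4 higher and 1.5 lower genes. FLG, LINC01108 and AMT kept both calls with any 1 library left out. Leaving out 1 of the WT or 40 kb iPSC libraries ended the 40 kb call of 5 of the 10 genes named here: NAA15, COL5A1, NID2, MAPK6 and PRAF2. The 100 kb call of 6 (PHF21B, MAGEA12, COL5A1, NID2, MAPK6 and PRAF2) was lost without a WT iPSC library or 100 kb iPSC replicate 2 or 3, and for MAGEA12, COL5A1, NID2 and PRAF2 also without some libraries of other groups. Removal of GC and length trends ended the 40 kb calls of NAA15, COL5A1, NID2 and MAPK6 and the 100 kb call of COL5A1. With iPSC fitted alone the 100 kb calls of MAGEA12, COL5A1, NID2, MAPK6 and PRAF2 and the 40 kb call of PRAF2 were lost. The replicate block ended the 100 kb calls of MAGEA12 and PRAF2, library totals the 40 kb calls of NID2 and PRAF2, no filter on low counts the 40 kb call of PRAF2, and thinning the 40 kb call of MAPK6 and the 100 kb call of MAGEA12. The correlation of fold changes across genes was 0.40 against 0.50 in the simulations, and the covariance 0.0453 against 0.0209, a difference of 0.0244. The count of 12 was 6 without WT replicate 2, 7 without 40 kb replicate 1 or 3, 74 without 100 kb replicate 1 and 7 without 100 kb replicate 3. It was 7 with iPSC fitted alone, 19 with the stricter filter, 314 with DESeq2 and 332 without a filter. The 3 WT libraries are too few to give each deletion its own 2, so part of any excess may come from the shared WT libraries.

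The deletion lines also differed from each other. In iPSC the 100 kb line had higher cholesterol synthesis genes than the 40 kb line, 16 of 24 members, such as INSIG1 (1.07 ± 0.12, adjusted p = 0.000192) and HMGCS1 (1.04 ± 0.15), and higher glycolysis and hypoxia genes, 17 of 34 (PKM, 0.44 ± 0.07), with ADM (-0.93 ± 0.12) and VEGFA (-0.87 ± 0.14), the latter named after its value was seen, lower. SLC7A11 (-1.73 ± 0.29), PSAT1 (-0.82 ± 0.17) and TRIB3 (-1.33 ± 0.29) of the stress list were lower, 8 of 30, and HSPA5 (0.48 ± 0.08) was among 3 that were higher, with SDF2L1 (0.57 ± 0.13) and CALR (0.26 ± 0.07), named after their values were seen. Camera gave adjusted p = 4.18e-14, 5.91e-07 and 0.0266 for these lists, and adjusted p = 0.236, 0.312 and 0.641 with an estimated correlation. Adjusted over the list alone, 19 cholesterol genes were higher, 21 glycolysis genes higher and 2 lower, and 7 stress genes higher and 13 lower. In all 1513 genes differed, 940 higher and 573 lower in the 100 kb line, 62.1% higher with TMM, 34.4% with library totals and, with TMM, 38.1% (83 higher, 135 lower) among changes of 2-fold or more. The count was 658 and 868 without 40 kb replicate 1 or 2, 697 without 100 kb replicate 1, 2610 with DESeq2 and 2298 without a filter.

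In NCC the pluripotency genes VRTN (0.67 ± 0.11, adjusted p = 0.0103), USP44 (0.59 ± 0.11), SOX2 (0.57 ± 0.11) and PRDM14 (0.86 ± 0.18) were higher in the 100 kb than in the 40 kb line, 6 of 36 in all. IER3 (-0.87 ± 0.18) and BAG3 (-0.50 ± 0.10) of the immediate early and heat shock list, and FN1 (-0.48 ± 0.10) and ADAM19 (-0.64 ± 0.14) of the migration list, were lower. Camera gave adjusted p = 1.74e-05, 5.55e-07 and 0.00013 for these lists, and adjusted p = 0.114, 0.196 and 0.207 with an estimated correlation. With p adjusted over the list alone, 16 pluripotency genes were higher and 4 lower, and 14 immediate early and 9 migration genes were lower. In all 207 genes differed, 90 higher and 117 lower, 43.5% higher with TMM, 54.2% with library totals and 58.8% among changes of 2-fold or more. The count was 328 and 25 without 40 kb replicate 1 or 2, 46 and 36 without 100 kb replicate 1 or 2, 797 with DESeq2 and 1092 without a filter.

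Differentiation in the deletion lines was compared with its course in WT. In the 40 kb line 13134 genes changed between NCC and iPSC, 6543 higher and 6591 lower, and in the 100 kb line 12497, 6274 higher and 6223 lower. In the 40 kb line library totals in place of TMM took the median of all genes from -0.037 to -0.18 and the share of called genes that were higher from 49.8% to 41.1%. Pluripotency genes fell in 35 and 33 of 36 members and crest specifiers rose in 22 and 23 of 30, and both lists passed in both lines (camera adjusted p = 2.95e-19 and 3.04e-19, and 2.37e-07 and 3.49e-08). They held with an estimated correlation (adjusted p = 0.00116 and 0.00116, and 0.00591 and 0.0035). Genes of neurons and glia rose in 15 of 27 members and fell in 6 and 7, and did not pass as a list (camera adjusted p = 0.237 and 0.0661), whereas placode genes rose in 22 and 19 of 29 (5.38e-07 and 2.03e-06, adjusted p = 0.0207 and 0.0342 with an estimated correlation). Adjusted over the list alone, 35 and 33 pluripotency genes fell, 23 and 23 crest specifiers rose, 15 and 15 neuron and glia genes rose, and 22 and 20 placode genes rose. In the interaction, which tests these differences of course directly, the neuron and glia list was lower (camera adjusted p = 6.97e-13 and 7.69e-15, adjusted p = 0.0202 and 0.0125 with an estimated correlation) and the pluripotency list higher (2.32e-09 and 3.05e-12, adjusted p = 0.0202 and 0.0072 with an estimated correlation). For crest specifiers it did not pass (0.79 and 0.834). Camera tests for a shift in 1 direction, and crest specifiers went both ways in deletion NCC against WT NCC. Their course is thus not shown to be unchanged.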

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

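The tests of dilution by iPSC, of a common proportion of iPSC transcripts, of copy loss, of fewer neuron-like cells and of the gap between the iPSC counts after removal of GC and length trends were chosen only after the results were seen. The NCC results below stand out because a deletion line's difference from WT differed between NCC and iPSC in edgeR's interaction test. The gap between the iPSC counts, taken up after them, involves no interaction. The interaction was called for 5078 genes in the 40 kb line and 3242 in the 100 kb line. Of the called genes 59.1% and 59.6% were higher with TMM and 32.8% and 43.7% with library totals, where the median of all genes went from 0.009 to -0.218 and from 0.011 to -0.103. Of the 20 genes of largest change in NCC named for each line, 17 in the 40 kb line and 19 in the 100 kb line passed. Of all tested genes 20.7% and 13.2% passed. The named genes were picked for large NCC changes, which enter the interaction, so a high share was likely from the start.

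In the 40 kb line the interaction was -0.88 ± 0.12 for ROBO1 (adjusted p = 5.07e-05), -2.85 ± 0.24 for ROBO2 (4.26e-07), -4.11 ± 0.16 for NEFM (7.37e-10), 2.56 ± 0.10 for PODXL (7.37e-10), -3.26 ± 0.13 for C14orf132 (7.37e-10), -4.33 ± 0.18 for COLGALT2 (8.24e-10) and 4.51 ± 0.19 for ESRG (8.24e-10). In the 100 kb line it was -0.50 ± 0.12 for ROBO1 (0.00837), -2.45 ± 0.23 for ROBO2 (2.46e-06), -4.07 ± 0.15 for NEFM (7.46e-10), 4.79 ± 0.19 for ESRG (7.46e-10), 2.46 ± 0.10 for PODXL (7.46e-10), -3.17 ± 0.13 for C14orf132 (7.46e-10) and 3.74 ± 0.16 for VRTN (7.46e-10).

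Pluripotency genes were higher and neuron and glia genes lower in NCC of both deletions than in WT NCC. Undifferentiated cells left in the cultures do not explain the neuronal fall by dilution: 29 pluripotency genes implied a median of 1.82% and 2.37% iPSC RNA, against 91.3% and 87.6% needed for median falls of -3.52 and -3.01. Nor did such cells account alone for the pluripotency genes, since the shares implied by the 10 most abundant ran from 0.432% (TDGF1) to 43.3% (PODXL) in the 100 kb line, a span of 100-fold, and from -0.809% (DPPA4) to 47.6% (PODXL) in the 40 kb line. PODXL stood apart, the next highest being DNMT3B at 8.94% and 7.88% in the 100 kb and 40 kb lines. These shares take leftover cells to hold each transcript at its iPSC level of day 0, so cells that had partly changed are not covered by either test. Depth was argued against by thinning every library to the smallest, after which 92.4% and 95.1% of the called genes were still called. Slower progress along the path of WT may account for part of the pattern: 72.4% (40 kb) and 77% (100 kb) of called genes moved against WT differentiation. At least 90% was set for it and under 75% in both lines against it. Among the 4619 and 3958 of these genes also called in WT differentiation, the shares were 76.9% and 81.7%, likewise between these bounds. A deviation shared by both WT NCC libraries would raise all these shares, so they do not decide the question.

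ROBO1 and ROBO2 were lower in NCC of both deletions than in WT NCC. A general shift of genes that rise on differentiation was argued against: among genes matched for level and rise, ROBO1 stood at percentiles 0.9 and 1.1 of 436 and ROBO2 at 2.5 and 3.3 of 120. Loss of a gene copy was argued against by iPSC, where the lowest fold change minus 2 SE was -0.55, above the -1 of a halved dose. Fewer neuron-like cells may account for the fall of ROBO2, which lay within the neuron and glia list, at percentiles 55.6 and 59.3 of its 27 genes (quartiles -4.45 to -1.31 and -3.96 to -1.13). These quartiles are wide, so a fall between them does not single out this explanation. ROBO1, at -0.89 and -0.65, lay above the upper quartiles and did not meet the same rule. Whether the deleted DNA acts on ROBO2 directly or the lower level follows from a change in cell types stays open. A difference between clones or differentiation runs, of WT or of the deletion lines, is not separated from either.

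Far more genes changed against WT in 40 kb iPSC than in 100 kb iPSC. Gain or loss of a chromosome was argued against, as the median farthest from 0 was -0.119, on chromosome 22, and windows with a shift held 1.1% of the calls. Of 16316 windows of neighbouring expressed genes, 34 were shifted in 40 kb iPSC and 0 in 100 kb iPSC. A gained or lost segment with far fewer expressed genes than a window could go unseen. Trends with GC content or length may account for part of the 40 kb count, which went from 2294 to 1417 genes, 1149 of them the same, as the median size of called changes went from 0.43 to 0.34 and the SE from 0.1 to 0.09. They were argued against as the whole cause of the gap, which was 2294 against 39 genes before and 1417 against 49 (28.9-fold) after their removal, and narrower with DESeq2 (3569 against 683) and without a filter (3189 against 844). The 10 splits of 6 libraries are too few for a share under 0.05: the real split gave 2294, 39 and 1513 genes for 40 kb against WT, 100 kb against WT and 100 kb against 40 kb, the highest other split 7, 3 and 2, and the real split alone (1) gave as many.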

How the results depend on the processing

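Library totals, removal of GC and length trends, and thinning were chosen only after the results were seen. Genes were followed under the alternatives if they were ROBO1, ROBO2, genes of largest change, shared genes or interaction genes. List members were followed where named for WT differentiation or a deletion against WT. List members named only for the deletions against each other, and genes named after their values were seen, were not followed as such. No called fold change of the followed genes changed sign under the alternatives run, but the balance of all called genes did. The share that were higher went from 58.1% to 35.5% (40 kb NCC), 57.9% to 37% (100 kb NCC), 45% to 63.4% (40 kb iPSC), 62.1% to 34.4% (100 kb against 40 kb iPSC) and 43.5% to 54.2% (the same in NCC) with library totals. With a threshold of 2-fold it went from 62.1% to 38.1% (100 kb against 40 kb iPSC), 43.5% to 58.8% (the same in NCC), 50.3% to 45.4% (differentiation of WT) and 50.2% to 45.2% (of the 100 kb line). In 40 kb iPSC it went from 45% to 50.9% without a filter and 51.3% without 100 kb iPSC replicate 1. In 100 kb iPSC it went from 25.6% to 65% with DESeq2 and 60% without 100 kb iPSC replicate 2. In 100 kb against 40 kb NCC it went from 43.5% to 60%, 65.2% and 80.6% without 40 kb NCC replicate 2 or 100 kb NCC replicate 1 or 2, and 52.8% without GC and length trends. Where values moved, the cause was not tested, except that fewer libraries leave fewer degrees of freedom and a 2-fold threshold admits fewer genes by construction.

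With a threshold of 2-fold, differentiation changed 8180 (WT), 7426 (40 kb) and 6855 (100 kb) genes, deletions against WT 194 and 15 in iPSC and 2528 and 2008 in NCC, the deletions against each other 218 (iPSC) and 68 (NCC), and the interactions 2460 and 1738, with overlaps of 3 (iPSC) and 1569 (NCC). ROBO1 did not reach 2-fold on differentiation of WT (0.55) or in NCC (-0.89 and -0.65). DESeq2 called 3569 (40 kb iPSC), 683 (100 kb iPSC), 2610 and 797 (100 kb against 40 kb, iPSC and NCC) and an iPSC overlap of 314. Without a filter the 100 kb iPSC count was 844, the 100 kb against 40 kb counts 2298 and 1092 and the iPSC overlap 332. The stricter filter gave an iPSC overlap of 19, and iPSC fitted alone 24 genes in the 100 kb line and an overlap of 7. Without GC and length trends 40 kb iPSC had 1417 genes.

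Leaving out 1 library gave 889 to 2779 genes in 40 kb iPSC, 16 to 121 in 100 kb iPSC, 4091 to 6126 and 3190 to 5073 in 40 kb and 100 kb NCC, 658 to 1627 and 25 to 328 for 100 kb against 40 kb in iPSC and NCC, and overlaps of 6 to 74 (iPSC) and 2626 to 4078 (NCC). ROBO2 in NCC ranged from -3.26 to -2.94 (40 kb) and from -2.38 to -2.22 (100 kb), and ROBO1 from -1.05 to -0.74 and from -0.69 to -0.60. Where an NCC group was left with 1 library, that library was assumed to vary like the other groups.

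ROBO1 and ROBO2 are left out of the next counts for WT differentiation and for the deletions against WT. The other cases of followed genes kept their side of the threshold 731 times with RLE scaling (3 stronger, 5 weaker), 625 with DESeq2 (63, 3) and 668 without a filter (66, 5). They did so 718 times with library totals (6, 15), 692 without GC and length trends (10, 37), 724 with the replicate block (4, 11) and 724 after thinning (3, 12). With only the libraries of the compared state or genotype it was 689 (6, 29), with the stricter filter 688 (13, 0) and with a threshold of 2-fold 559 (0, 180). Of 33 pairs of groups' libraries sharing a number, residual correlations ran from -0.157 to 0.17, so numbers were not taken as pairs. Between iPSC and NCC of the same genotype they ran from -0.007 to 0.019. The block gave 2118, 37, 5724 and 4717 genes for the deletions against WT in iPSC and NCC. It takes a number as shared by all genotypes, so pairing within a genotype was not fitted. For gene lists, an estimated correlation ended 117 calls, fry ended 20 and added 63.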

Other observations

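The genes here were chosen after their values were seen. ZNF736, a zinc finger gene, measured 9.57 ± 1.11 CPM in WT, 0.15 ± 0.106 in 40 kb and 21.6 ± 4.45 in 100 kb iPSC, and 9.02 ± 0.945, 0.0497 ± 0.0257 and 25.7 ± 5.05 in NCC. FLG, encoding filaggrin, measured 19.7 ± 1.87 CPM in WT NCC, 2.52 ± 1.12 in 40 kb and 2.35 ± 0.75 in 100 kb NCC. CTSF, a lysosomal protease gene, was lower in the 40 kb line in iPSC (-3.19 ± 0.22) and NCC (-4.58 ± 0.33), and measured -0.08 and 0.09 in the 100 kb line. The clones are not given in the sources used here, so a difference between clones is not separated from the deletion. This holds for ZNF736, FLG and CTSF and for every other gene compared between a deletion line and WT. The imprinted gene IGF2 measured 293 CPM in WT iPSC replicate 1 and 29.6 and 26.6 in replicates 2 and 3. WT iPSC replicates 1, 2 and 3 held 0, 0.705 and 0.662 CPM of the crest gene NR2F1, and 0.0756, 0.374 and 0.722 of PAX3.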
